A study of Mus musculus with 6 samples.

How the data were processed

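Hi-C was carried out on mouse embryonic stem cells of strain 129. Per the labels' protocols, crosslinked nuclei were cut with MboI, the ends were filled in with a biotin-labelled nucleotide and ligated inside the nuclei, and the sonicated DNA was made into sequencing libraries. There were 6 libraries, 3 labelled wild type (WT) and 3 labelled Del8, for CTCF without zinc finger 8. The series' design text describes both lines as expressing a CTCF protein, GFP-tagged CTCF or the mutant, and speaks of biological replicates. Whether the libraries labelled wild type carry the GFP tag is not settled by the labels, and the label WT is used here. Each replicate number came from the library's title.

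The authors deposited raw contact counts for pairs of 50 kb bins, 1 file per library. The build was mm10 per the submitters' processing notes. The aligner, the filtering of read pairs and any filtering of bins are not given in the sources used here. The files held whole-number contact counts of pairs on the same chromosome, the diagonal included, for the 19 autosomes, X and the mitochondrial genome. Contacts between chromosomes were not analysed here, so the planned comparison of the share of contacts within chromosomes was left out. Gene positions came from a RefSeq table of the same build, which gives no strand, so a gene's start means its lower coordinate and not its transcription start site.

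The libraries held 24038030, 24512722 and 36233407 contacts (WT replicates 1 to 3) and 66266759, 46925260 and 38088173 (Del8 replicates 1 to 3). The median contact count per usable 50 kb bin was lowest in WT replicate 1, at 1294, and highest in Del8 replicate 1, at 2898. No pair of libraries agreed within sampling noise in the coverage of usable bins (chi-square per degree of freedom 1.81 or more), so none was a copy of another. This does not show that they are independent. Each was counted as a replicate, and the series' design text speaks of biological replicates. By this measure WT replicate 3 lay nearer to Del8 replicates 1 to 3 (3.21, 2.79 and 2.85) than to WT replicates 1 and 2 (4.82 and 5.28).

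Bins were screened because many had lost their contacts in some libraries. Coverage was scaled in each library to its well-covered bins. A bin was usable if its scaled coverage in every library was at least 0.5 of the third highest of the 6 libraries and above 0.1 of that library's own scale. Of 47875 autosomal bins with contacts, 27803 (58.1%) were usable. They held the starts of 81.2% of autosomal protein-coding genes, so gene-poor regions are under-represented. Chromosome X entered only the comparison of chromosome coverage and the contact shares by distance. The screen was set after the data were examined. A looser screen, which asks only for 20 or more contacts per library, left 45645 bins and is given as an alternative.

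Maps were balanced per chromosome by iterative correction with the diagonal left out. The insulation score of a bin was log2 of the mean balanced contact in a 500 kb square across it, over the chromosome's mean, with at least 50% of the square usable. A higher score at a boundary means more contact across it relative to the chromosome's mean. Boundaries were local minima with a prominence of 0.2 or more on the map summed over the 6 libraries. Boundary strength per library was the mean of the score at boundaries minus that 250 kb to either side. Domains were stretches of 200 kb to 2 Mb between successive boundaries. Observed contact was divided by the mean at the same distance on the same chromosome.

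Compartments were taken at 250 kb. The eigenvector was 1 of the first 3 principal components, the one correlating best with gene density, which also set its sign. Each chromosome was scaled to SD 1. The planned design did not say from which matrix it is computed. The matrix was chosen after the maps were examined and before any test of single bins. In the first version, from the correlation matrix of observed over expected contact, every library reached a correlation of 0.9 with the summed map on only 1 of 8 chromosomes. Then 4 versions were compared on 8 chromosomes by how well each library's eigenvector correlated with that of the summed map. The centred correlation matrix was taken, for which every library reached a correlation of 0.9 or more on 5 of these chromosomes, against 1 to 3 for the other versions. Its mean correlation (0.732) was not the highest: the correlation matrix of log values had 0.817. Calls under all versions are given. On all 19 autosomes, 12 met the limit of 0.9 in every library and 7 did not. A fit restricted to those 12 was once treated as the primary one. After its calls had been seen, it was returned to the status of an alternative because the planned test covers all valid bins.

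Single values per library were compared by the two-sided exact permutation test, whose smallest possible p for 3 against 3 is 0.10. Insulation scores, eigenvectors and chromosome shares were tested with limma 3.58.1 without trend. Counts of 100 kb bin pairs 100 kb to 2 Mb apart, with a mean count of 10 or more, were tested with the quasi-likelihood test of edgeR 4.0.16, with offsets per chromosome and distance. P-values were adjusted by Benjamini-Hochberg, at a threshold of 0.05. DESeq2 1.42.0 was an alternative. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

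The tests, the gene lists, most alternatives and the rule for named items were fixed before the data were examined. The rule took, among boundaries past the threshold whose groups did not overlap, the 10 largest rises and the 10 largest falls of score, with up to 2 protein-coding genes starting in the bin. For compartments it took 8 bins each way that changed sign, and for bin pairs the 5 largest changes each way, at most 1 per 2 Mb. Where nothing passed, the 3 smallest p were taken. From each of 12 gene lists, the 3 members with the largest change in insulation and in eigenvector were taken whether or not they passed. Members in the same bin count once. Added after the data were examined were: leaving out WT replicates 1 and 2 together (which leaves 1 WT library and takes the spread from Del8 alone), keeping partly lost bins, counting usable bins only, the other eigenvector versions, the restriction to 12 chromosomes, and contact by the number of boundaries crossed.

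The steps were tested on simulated data. On a simulated map all 56 boundaries were found within 1 bin. With values drawn for the 1247 real boundaries, limma recovered 94.0% of the boundaries changed by 0.3 and 18.0% of those changed by 0.1. For the 22019 bins with a score, it recovered 84.0% of changes of 0.3 and 0% of changes of 0.1. For the 5587 bins with an eigenvector, it recovered 49.0% of changes of 1 SD and 7.0% of changes of 0.5 SD. For 152352 bin pairs, edgeR recovered 19.4% of 1.5-fold changes, 67.2% of 2-fold changes and 81.8% of 3-fold changes. Only 100 boundaries or bins of each size, and 66 or 67 pairs, were changed. For insulation and bin pairs the data gave far more calls, so the adjusted threshold was stricter in the simulation. These rates therefore do not give the smallest change that could pass. In the data the bin of Hoxc6 passed at 0.085 (limma, adjusted p = 0.034).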

Results

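Contact maps of mouse embryonic stem cells were made by in-situ Hi-C, which counts how often 2 stretches of DNA are ligated to each other in crosslinked nuclei. Of the 6 libraries, 3 came from cells labelled wild type (WT) and 3 from cells whose CTCF lacks zinc finger 8 (Del8). CTCF is a zinc finger protein that binds DNA and, with cohesin, marks the borders of chromatin domains. The title of the series ties the residence time of CTCF on chromatin to the folding of the genome, so the question of the Hi-C was which levels of folding differ between the 2 lines. The libraries held from 24038030 (WT replicate 1) to 66266759 contacts (Del8 replicate 1), all within chromosomes, at a resolution of 50 kb. All positions are on mm10.

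The WT libraries were not alike in the regions they covered. WT replicates 1 and 2 were short of contacts in 37.6% and 38.1% of 47875 autosomal bins, against 0.0752% in WT replicate 3. The Del8 libraries were short in 0.0355%, 0.0648% and 9.30% of bins. Short bins of WT replicates 1 and 2 held 15.8% and 14.1% of the expected contacts. All tests of boundaries, compartments and bin pairs were therefore restricted to 27803 bins usable in all 6 libraries. The WT libraries also differed in the share of contacts within 1 bin, at 31.2%, 30.7% and 22.3% in replicates 1 to 3. It was 26.5%, 26.4% and 26.6% in Del8 replicates 1 to 3.

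**Figure D1:**
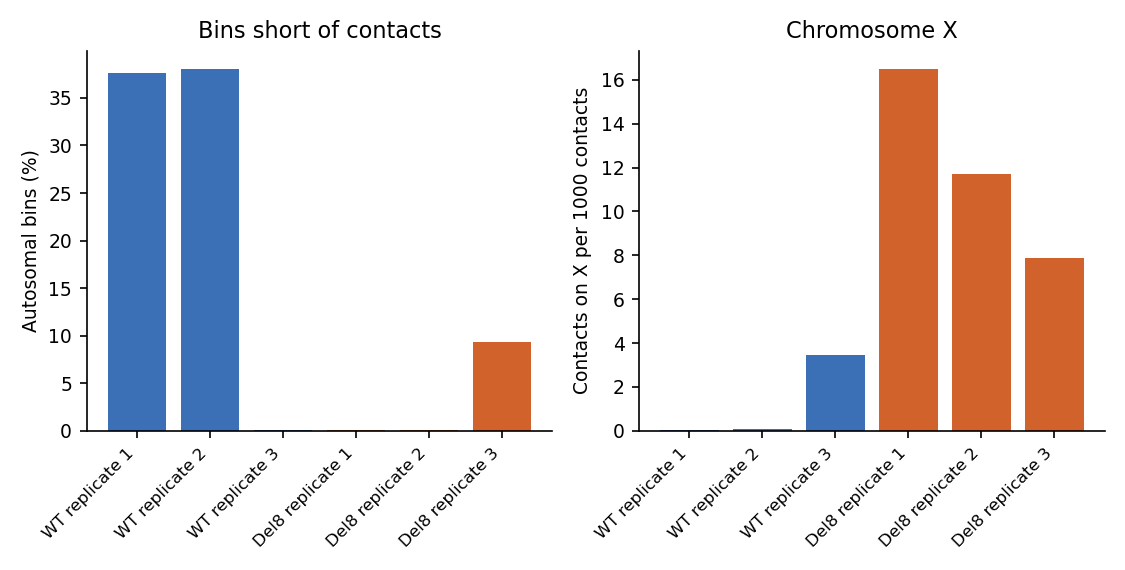
Left, percent of autosomal 50 kb bins short of contacts in each library; right, contacts on chromosome X per 1000 contacts. Bars are single libraries, WT in blue and Del8 in orange: WT replicates 1 and 2 stand apart at 37.6% and 38.1% of bins, and have almost no contacts on X.

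Domain boundaries separated their flanks less in Del8 cells. Of 1247 boundaries, 642 (51.5%) had a higher insulation score in Del8 and 170 (13.6%) had a lower one. A higher score is more contact across the boundary relative to the chromosome's mean. The median score rose by 0.11 on the log2 scale, a 1.08-fold contact on this relative scale. Among boundaries that became weaker the median relative contact was 1.17-fold that of WT, and among those that became stronger 0.893-fold. The groups did not overlap at 68.6% of boundaries, where chance gives 10% for a single boundary. Boundaries of a library can shift together, so this share is not a test over 1247 independent boundaries. Boundary strength, the mean score at boundaries relative to 250 kb on either side, was -0.56 ± 0.03 in WT and -0.45 ± 0.0051 in Del8 (SD, n = 3 each). No WT library reached the level of a Del8 library (two-sided exact permutation test, p = 0.10, the smallest that 3 against 3 can give). Called on each library's own map, boundaries numbered 1390, 1383 and 1287 in WT and 1177, 1177 and 1178 in Del8.

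The balance of weaker and stronger boundaries depended on how libraries were centred. With each library centred on the median of its boundaries, 376 boundaries were higher and 394 lower in Del8; such centring by itself brings the numbers above and below close to each other. Without WT replicates 1 and 2 the counts were 518 and 204. That fit, here and below, sets a single WT library against 3 of Del8, so its spread comes from Del8 alone and its calls are not a test of stability. Keeping partly lost bins ended all calls (limma, 0 of 1874 boundaries, with 320 at an unadjusted p under 0.05), while the difference in boundary strength there was 0.28, against 0.10, and the groups did not overlap (exact permutation test, p = 0.10). For boundaries taken from the Del8 map alone, strength was -0.49 in WT replicate 3 and -0.49, -0.48 and -0.49 in the Del8 libraries, so the groups overlapped there.

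**Figure D2:**
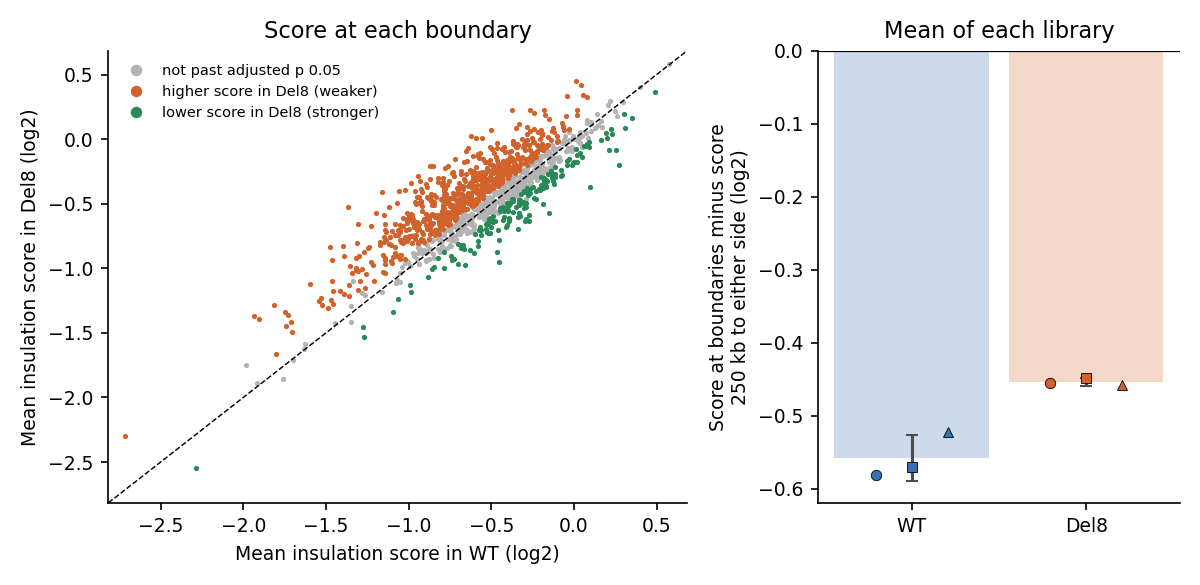
Left, mean insulation score (log2) of each of 1247 boundaries in WT against Del8, with 642 boundaries of higher score in Del8 in orange, 170 of lower score in green and the diagonal dashed. Right, strength of boundaries per library (log2; bars are means, error bars SD, n = 3), with all Del8 libraries nearer to 0 than any WT library.

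The largest rise of score lay on chromosome 6 at 143200001 to 143250000, in a bin without the start of a protein-coding gene. Its score was -1.37 ± 0.05 in WT and -0.52 ± 0.03 in Del8 (SD, n = 3 each), a difference of 0.84 (limma, SE 0.04, adjusted p = 1.88e-07). That is a 1.79-fold contact across it relative to the chromosome's mean. The boundary on chromosome 17 at 66500001 to 66550000, also without a gene start, rose by 0.75, a 1.69-fold contact on the same scale. On chromosome 4 at 141050001 to 141100000, the bin with the starts of Necap2, which codes for an adaptor-binding protein of endocytosis, and Spata21 rose by 0.66 from -1.06 ± 0.07. Of the other 7 largest rises, those with a gene start were bins on chromosome 1 at 172350001 to 172400000 with Pigm, a mannosyltransferase of the GPI anchor pathway, and on chromosome 3 at 51450001 to 51500000 with Rab33b, a small GTPase of the Golgi. They rose by 0.65 and 0.64. The other 5 of the 10 largest rises had no protein-coding gene start and ranged from 0.64 to 0.66: chromosome 1 at 186750001, chromosome 11 at 104250001, chromosome 15 at 12900001, and chromosome 8 at 95900001 and at 60450001.

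The largest fall of score, to a stronger boundary, was on chromosome 1 at 179800001 to 179850000. The score there fell from -0.45 ± 0.03 in WT to -0.95 ± 0.04 in Del8, a difference of -0.50 (SE 0.04, adjusted p = 1.29e-06). With a 250 kb square this boundary no longer passed (limma, -0.13, adjusted p = 0.068). A dip nearby, at 179500001 to 179550000, was shallower in Del8. Scores there were -0.86, -0.66 and -0.64 in WT replicates 1 to 3 and -0.52, -0.39 and -0.52 in Del8 replicates 1 to 3. Falls with gene starts in the bin were found at Surf4 and Stkld1 on chromosome 2 (26900001 to 26950000, -0.42), where 6 genes start, and at Syt2, a calcium sensor of vesicle release, on chromosome 1 (134600001 to 134650000, -0.37). They were also found at Gorasp1, a Golgi stacking protein, and Ttc21a on chromosome 9 (119900001 to 119950000, -0.36) and at 1700093K21Rik on chromosome 11 (23500001 to 23550000, -0.34). The other 5 of the 10 had no protein-coding gene start: chromosome 4 at 105650001 (-0.47), chromosome 9 at 66450001 (-0.47), chromosome 14 at 27500001 (-0.41), chromosome 3 at 9350001 (-0.34) and chromosome 17 at 66150001 (-0.33). Keeping partly lost bins turned the direction at the Surf4 bin (1.42) and at the bin on chromosome 14 (0.83), neither past the threshold there.

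**Figure D3:**
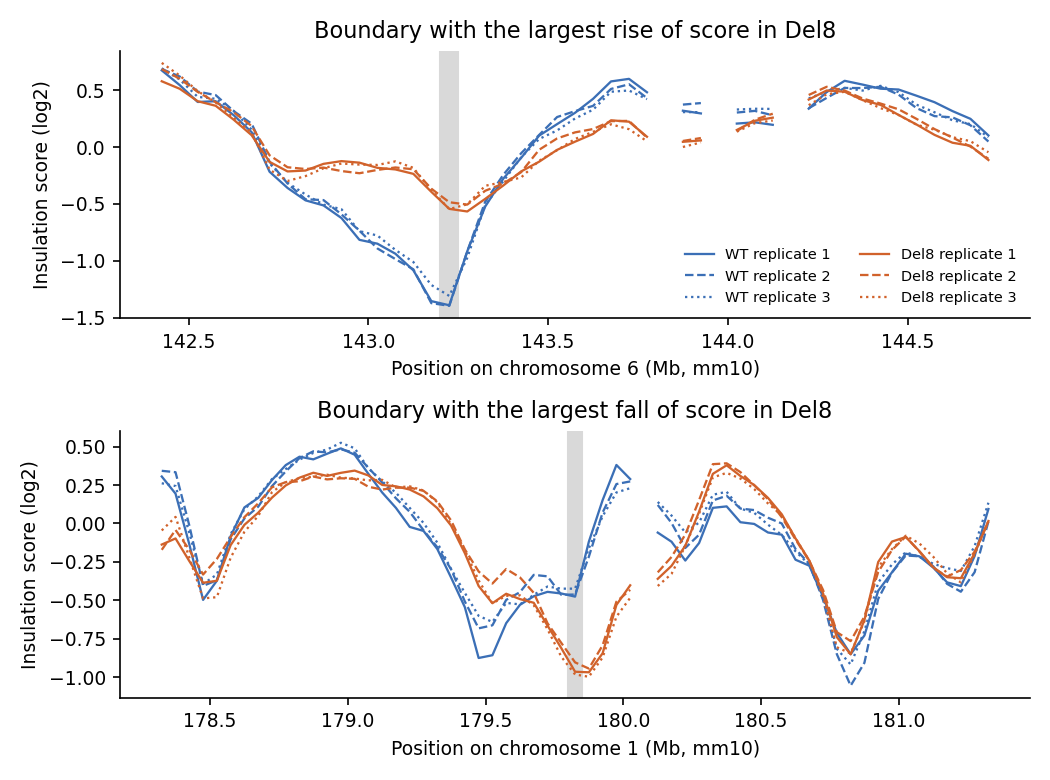
Insulation score (log2) against position (Mb) for the 6 libraries around the boundary with the largest rise (chromosome 6, top) and the largest fall (chromosome 1, bottom) in Del8, each boundary bin in grey; gaps are bins without a score. At the top the 3 Del8 lines lie near -0.52 in the grey bin and the 3 WT lines near -1.37.

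The gene lists fixed beforehand were read from the 50 kb bin of each gene's start. Over all bins with a score, 7164 rose and 6705 fell among 22019, and neighbouring bins share most of their square and are not independent. Of 18 bins with pluripotency genes 11 rose, 1 fell and 6 did not pass, and the counts adjusted over the list alone were the same, 11 and 1. The share of changed bins in this list was not past the threshold against all bins (Fisher's exact test, p = 0.812, adjusted p = 0.894 over 11 lists). The largest change was at Dppa3, a maternal factor also expressed in naive stem cells (chromosome 6, 122626424 to 122630271). Its bin, a boundary, went from -0.59 ± 0.12 in WT to 0.0062 ± 0.04 in Del8 (SD, n = 3 each), a difference of 0.60 (SE 0.05, adjusted p = 2.66e-06). The bin of Utf1, a chromatin factor of pluripotent cells, rose by 0.39. That of Nanog, a core pluripotency transcription factor on chromosome 6, rose by 0.29. All 7 measured bins of the DNA methylation list rose, and all 7 adjusted over the list alone: Tet3 rose by 0.34 and Tet1 by 0.26, both coding for enzymes that oxidise methylcytosine, and Uhrf1, which recruits the maintenance methyltransferase, by 0.23. The share of changed bins in that list was not past the threshold against all bins (Fisher's exact test, p = 0.0516, adjusted p = 0.567), nor was that of any other list. With all 7 bins changed no larger share was possible, so the test could not show an excess in this list. The same holds for the fibroblast list, where all 4 measured bins changed. The test counted rises and falls together, so the share that rose was not tested against 7164 of 22019.

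Genes of other lineages went both ways. Of 9 trophectoderm bins 6 rose and 0 fell, with Krt8 and Krt18, keratins of simple epithelia, up by 0.33 and 0.31, and Eomes, a T-box transcription factor, up by 0.22. Of 7 primitive endoderm bins 3 rose and 1 fell. Pdgfra, the receptor for platelet-derived growth factor, rose by 0.35 at a boundary bin, Col4a1, a basement membrane collagen, by 0.20, and Gata4 by 0.12. Of 6 neural bins 2 rose and 3 fell, with Neurog2 up by 0.30, Sox1 at -0.19 and Otx2 at -0.13. Of 4 fibroblast bins, a list kept for feeder cells, 3 rose and 1 fell, with Fbn1 up by 0.34, Col1a1 by 0.15 and Thy1 by 0.14. For these 4 lists and for those below except the one of CTCF and cohesin, the counts adjusted over the list alone were the same. With WT replicate 3 as the only WT library the differences of Gata4 and Otx2 were 0.09 and -0.06, and Otx2 did not pass without Del8 replicate 3.

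Genes in clusters and imprinted genes also went both ways. Of 13 protocadherin bins 4 rose and 6 fell. The bins of Pcdhga8 with Pcdhgb4, of Pcdhga12 and of Pcdhgc3 with Pcdhgc5, adhesion molecules encoded side by side on chromosome 18, rose by 0.52, 0.51 and 0.44. Of 13 Hox bins 8 rose and 1 fell, with Hoxb6 and Hoxb9 in 1 bin up by 0.18, Hoxa13 by 0.17 and the bin of Hoxa5, Hoxa7 and Hoxa9 by 0.16. With WT replicate 3 as the only WT library the differences of the Hoxa bins were 0.07 and 0.03, and the bin of Hoxa5 did not pass without any 1 of WT replicate 1, WT replicate 2 or Del8 replicate 2. Of 21 bins of imprinted genes 6 rose, 4 fell and 11 did not pass. Impact, at a boundary on chromosome 18 (12954690 to 12992950), rose by 0.58 from -1.07 ± 0.04. The bin of Kcnq1ot1, a non-coding RNA of an imprinted domain, was at -0.36, and that of Copg2 and Mest at -0.35. Of 11 bins of CTCF and cohesin genes 2 rose and 3 fell, and adjusted over the list alone 1 rose and 3 fell. Ctcfl, the germline paralogue of CTCF, rose by 0.24, while Smc3, a cohesin subunit, was at -0.21 and Esco1, a cohesin acetyltransferase, at -0.15. The only measured two-cell-like gene, Sp110, was at -0.0050 (adjusted p = 0.93), and no gene of the X-inactivation centre was measured, since X was left out.

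Contacts at intermediate distances were more frequent in Del8 cells. Of contacts between different bins of a chromosome, 20.2% ± 0.699 lay at 500 kb to under 2 Mb in WT and 22.9% ± 0.0565 in Del8 (SD, n = 3 each). The groups did not overlap (two-sided exact permutation test, p = 0.10, adjusted p = 0.40 over 4 bands, where 0.10 is the smallest p possible). The bands at 50 kb to under 500 kb (48.8% ± 3.95 and 48.1% ± 0.835), 2 Mb to under 10 Mb (11.7% ± 0.898 and 11.4% ± 0.249) and 10 Mb or more (19.3% ± 2.35 and 17.7% ± 0.612) overlapped. On ICE-balanced maps (-2.27) and on usable bins (-2.41) every Del8 library was below every WT library in the last of these. WT replicate 3 set much of the WT spread, with 44.2% of contacts in the shortest band and 22.0% in the longest. The difference in the shortest band, -0.670, was 3.88 without WT replicates 1 and 2, and it was also above 0 without either of them alone.

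**Figure D4:**
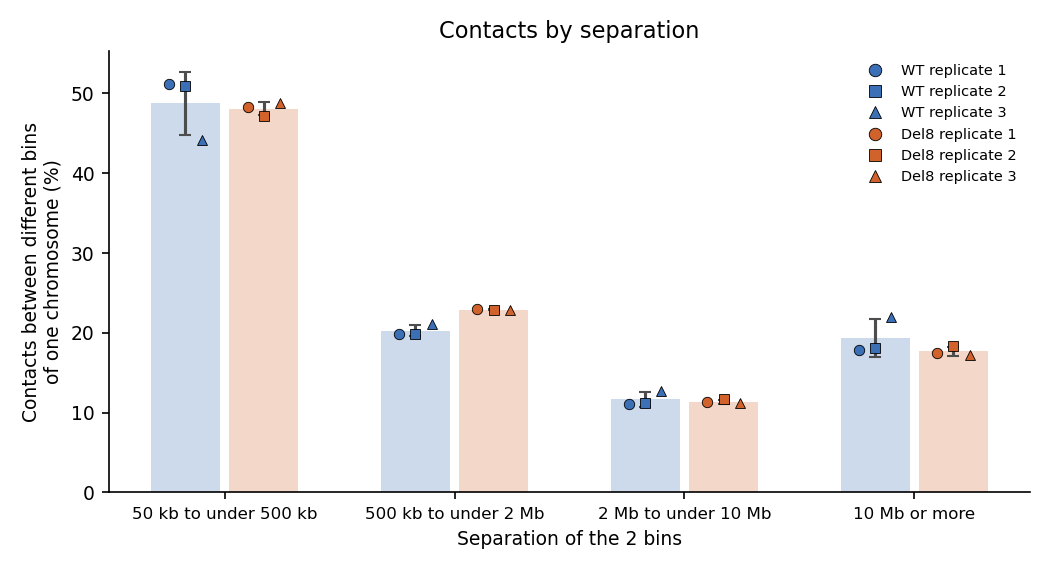
Percent of contacts between different bins of a chromosome in 4 ranges of separation. Points are libraries, bars means and error bars SD (n = 3 each): at 500 kb to under 2 Mb all Del8 libraries (22.8% to 22.9%) lie above all WT libraries (19.8% to 21.1%).

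Domains were less enriched for their own contacts in Del8. Over 1012 domains, observed over expected contact within domains was 1.12 ± 0.0088 in WT and 1.08 ± 0.0024 in Del8 (SD, n = 3 each). Between adjacent domains it was 0.814 ± 0.0069 and 0.839 ± 0.0016. Neither measure overlapped between the groups (two-sided exact permutation test, p = 0.10 each, adjusted p = 0.15 over 3 values). With partly lost bins kept, the difference within domains was -0.155, against -0.0418, and the groups overlapped. Between adjacent domains it was then 0.103, against 0.0251, without overlap. The corner of a domain, where its 2 boundaries meet, had 1.14 ± 0.0096 and 1.13 ± 0.0086 times the contact of its domain, and the groups overlapped (exact permutation test, p = 0.40).

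Pairs of bins were then divided by the boundaries between them, a division chosen after the data were examined. At 500 kb to under 2 Mb, balanced contact was 1.06-fold higher in Del8 for pairs with no boundary between them, 1.17-fold with 1 boundary and 1.22-fold with 2 or more. At 100 to 450 kb it was higher by 0.14 on the log2 scale for pairs with 1 boundary between them. In these 4 classes every Del8 library was above every WT library (two-sided exact permutation test, p = 0.10 each, adjusted p = 0.125 over 5 classes). At 100 to 450 kb without a boundary the groups overlapped (1.00-fold, exact permutation test, p = 1).

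**Figure D5:**
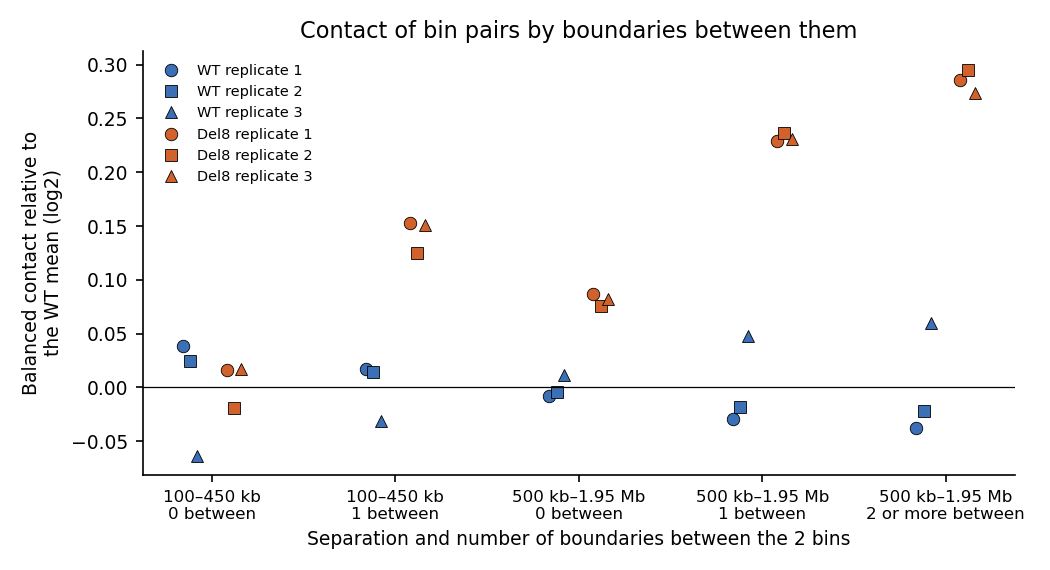
Balanced contact of bin pairs relative to the WT mean (log2), by separation and by the number of boundaries between the 2 bins; each point is a library. The gap between Del8 and WT is 0.08 without a boundary at 500 kb to under 2 Mb and 0.28 with 2 or more.

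Single bin pairs differed in both directions once chromosome and distance were taken out. Of 152352 pairs of 100 kb bins, 7210 had more contacts in Del8 and 6241 fewer (edgeR, adjusted p under 0.05). The median change was 1.59-fold for pairs that rose and 1.48-fold for pairs that fell. A boundary lay between the bins in 58.6% of pairs that rose and 31.1% of pairs that fell, against 64.2% of all pairs tested. At 100 to 400 kb, 12.6% of pairs with a boundary between them rose and 3.20% fell, against 6.34% and 7.37% of pairs without one. At 500 to 900 kb the share that rose was 5.53% with a boundary and 5.82% without, while 913 of 32164 and 1521 of 15148 pairs fell. At 1 to 2 Mb 1.94% with a boundary and 1.38% without one rose, and 1.23% and 5.84% fell. The counts were 2393 and 2075 without WT replicates 1 and 2, 2200 and 4136 with DESeq2, and 7038 and 8230 with TMM factors in place of the offsets.

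The pair with the largest rise joined chromosome 12 at 71600001 to 71700000 with 73400001 to 73500000, with 3, 2 and 1 contacts in the WT libraries and 22, 21 and 19 in the Del8 libraries (log2 fold change 2.56, SE 0.55, adjusted p = 0.00044). A bin with Gm13889 and Alkbh3, a nucleic acid demethylase, on chromosome 2 (93900001 to 94000000) gained contact with the region at 94500001 to 94600000 across 1 boundary, from 4, 4 and 7 contacts to 63, 46 and 32 (log2 fold change 2.37). All counts here are raw, while the fold changes take the offsets into account. The mean count per pair was 53.2, 55.5 and 67.3 in WT and 126, 88.7 and 76.9 in Del8, replicates 1 to 3. On chromosome 9 the bin of Polr2m gained contact with that of Nedd4, a ubiquitin ligase, 1200 kb away (2.28). A pair on chromosome 10 at 93300001 and 95000001 rose by 2.37. The pairs on chromosomes 12, 10 and 9 held 3 or fewer contacts in every WT library. They met the mean count of 10 only through their Del8 counts. On chromosome 5 the bins of Smok3c and Smok3b and of Lamtor4 and Map11 had 0 contacts in WT replicates 1 and 2 and 17 in WT replicate 3, and this pair did not pass without the first 2 (0.90). The pairs on chromosomes 10 and 9 did not pass without them either (2.13 and 2.22). The largest falls were between Tnfaip8l3 and Etfa, and between the bin of Stoml1 and Pml, which codes for the scaffold of PML nuclear bodies, and that of Pkm, pyruvate kinase, and Gramd2, both on chromosome 9 (log2 fold change -1.76 and -1.75). They were followed by Fam13b and Pkd2l2 with Cxxc5 on chromosome 18 (-1.74), the bin of Tmem38b on chromosome 4 with a region 900 kb away (-1.68) and Arhgap21 with Pdss1 on chromosome 2 (-1.64). Counts were low for Tnfaip8l3 with Etfa, at 13, 12 and 17 in WT and 9, 11 and 2 in Del8. Those of the Tmem38b pair were higher, at 48, 39 and 40 in WT and 30, 27 and 17 in Del8. Both falls on chromosome 9 and that of Arhgap21 did not pass without WT replicates 1 and 2. The fall of Cxxc5 did not pass without WT replicate 3 (-1.46), nor that of Arhgap21 without WT replicate 2 (-1.32) or Del8 replicate 2 (-1.41).

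The large-scale compartments are active (A) and inactive (B) chromatin, and the maps left open whether they differ between the lines. Compartment strength was 2.54 ± 0.167 in WT and 2.41 ± 0.0592 in Del8 (SD, n = 3 each), and the groups overlapped (two-sided exact permutation test, p = 0.30). Contact among A bins was lower in every Del8 library, at 1.57 ± 0.0327 in WT and 1.44 ± 0.0047 in Del8 times the expected level (exact permutation test, p = 0.10). The strength difference, -0.126, ranged from -0.222 (without WT replicate 3, where the groups did not overlap) to -0.0713 without 1 library. It turned to 0.0664 without WT replicates 1 and 2. With partly lost bins kept it turned to 0.781 without overlap, and that among A bins turned to 0.0643.

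No 250 kb bin passed the test of the compartment eigenvector. Of 5587 bins, limma called 0, with 837 at an unadjusted p under 0.05 where chance alone gives 279. The sign of the mean was the same in both groups in 89.5% of bins. The count depended on the version of the eigenvector: 303 bins rose and 600 fell with the correlation matrix, 259 and 134 with that of log values, and 0 and 0 with observed over expected minus 1. On the 12 chromosomes where every library correlated at 0.9 or more with the summed map, 100 rose and 93 fell. The smallest p belonged to bins that did not pass: Ankrd50 on chromosome 3 (38250001 to 38500000, difference -1.95), Adam30 and Reg4 on chromosome 3 (98000001 to 98250000, 1.67) and Syne3 and Clmn on chromosome 12 (104750001 to 105000000, from 0.43 to 1.93), each with an adjusted p of 0.068. Both chromosomes are among the 7 where at least 1 library correlated below 0.9 with the summed map, down to -0.0392 on chromosome 3 and 0.872 on chromosome 12.

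Eigenvectors of the gene lists gave no call over all bins. Among the members with the largest differences were, for pluripotency, Prdm14 (0.66), Tfcp2l1 (-0.62) and Utf1 (0.56), and for the two-cell-like list Sp110 (0.42) and Tcstv1 (-0.03). In the protocadherin cluster they included the bins of Pcdhga12 (-0.53), Pcdha12 (0.49) and Pcdhb1 (-0.32), among Hox genes those of Hoxa13 (-0.47) and Hoxc10 (0.38), and among imprinted genes Gnas (0.49), Grb10 (-0.43) and Nnat (-0.35). Trophectoderm genes gave Tfap2c (0.50), Krt8 (0.36) and Elf5 (-0.31), and primitive endoderm genes Pdgfra (-0.66) and Sox7 (0.58). Neural genes gave Neurog2 (1.06), Olig2 (0.52) and Nes (-0.26), and fibroblast genes Tbx15 (1.14), Twist2 (-0.64) and Prrx1 (0.25). The list of CTCF and cohesin gave Ctcfl (0.61), Pds5a (-0.55) and Pds5b (0.32), and DNA methylation Tet2 (1.00), Tet1 (-0.51) and Tet3 (-0.30). Neurog2, Tbx15, Nes and Tet2 lie on chromosome 3, where libraries took different components, and the SD of Neurog2 was 1.39 in WT. Tcstv1, Hoxa13, Sox7, Olig2, Tet1 and Tet3 also lie on chromosomes where at least 1 library correlated below 0.9 with the summed map. Adjusted over the list alone, 1 bin was higher in the two-cell-like list, and 1 was lower in each of the lists for primitive endoderm, fibroblasts and CTCF and cohesin.

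No chromosome passed the test of its share of contacts (limma, 0 of 20, with 1 at an unadjusted p under 0.05, chromosome X at an adjusted p of 0.28). Without WT replicate 3, 2 chromosomes were higher and 16 lower in Del8. Chromosome 8 had the highest median coverage per usable bin in both groups, 1.34 ± 0.0438 in WT and 1.25 ± 0.0161 in Del8 times that of the median chromosome (SD, n = 3 each). Its coverage ranged from 1.24 to 1.38 over the 6 libraries. Of its bins 88.8% were usable, against 58.1% over all autosomes. The test compares the groups, so it cannot show a higher coverage shared by both lines, and copy number was not tested. Counted on usable bins, 0 of 19 autosomes passed, with 6 at an unadjusted p under 0.05.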

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

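The tests of the coverage filter, of random ligation and of the contact share on usable bins were chosen only after the result was seen, as was the use of the planned thinning as a test of depth.

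Contacts on chromosome X, which entered few comparisons, made up 16.5, 11.7 and 7.87 per 1000 contacts in Del8 replicates 1 to 3. In WT replicates 1 to 3 they made up 0.0570, 0.0980 and 3.46. The share rose in the order of total contacts through all 6 libraries, so depth and line cannot be told apart. X was sparse in Del8 too: its median bin with contacts held 445, 49 and 20, against 2128, 1530 and 1297 per autosomal bin. A coverage filter on bins before the maps were made may account for the near absence in WT replicates 1 and 2. Such a filter would remove the bins of lowest coverage, and an autosomal bin kept in WT replicate 1 had higher coverage in Del8 replicate 1 than a short one with a chance of 0.950. Any loss that grows as coverage falls would give such a value, so it does not single out a filter. Short autosomal bins of WT replicate 1 still held 15.8% of the expected contacts, which a filter removing whole 50 kb bins would not leave. A difference in the number of X chromosomes between the lines was not tested.

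Weaker boundaries in Del8 were weighed against 3 technical explanations. Lost bins would spare boundaries whose surroundings are fully usable, yet at 766 such boundaries the median score still rose by 0.10 (394 higher, 111 lower). Depth would vanish with thinning, and the difference in strength after thinning was 0.10. A higher random ligation background would raise contacts at 10 Mb or more, and their share on usable bins was not higher in Del8 (-2.41 percentage points; over all bins -1.66 with overlapping groups, and -0.304 without WT replicate 3). These values bear only on the 3 explanations named, and random ligation was read from contacts within chromosomes alone. The loss of zinc finger 8 and any difference in preparation between the lines cannot be told apart as a cause of the weaker boundaries. Keeping partly lost bins left 0 boundaries past the threshold while the difference in strength was 0.28.

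The gain of contacts at 500 kb to under 2 Mb was set against leak across weakened boundaries alone, which predicts no gain for pairs without a boundary between them. Such pairs gained 0.0818 on the log2 scale. That does not decide whether leak alone makes up the gain, since boundaries that were not called may lie between these bins. With a 250 kb square 1913 boundaries were called, against 1247 here. On bins usable in all 6 libraries the share still rose by 2.51 percentage points, so bins that failed the screen do not explain the gain.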

How the results depend on the processing

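The alternatives without WT replicates 1 and 2, with partly lost bins kept, on usable bins only, on 12 chromosomes, and with other eigenvector versions were chosen after the data were seen. Boundary strength, contact within and between domains, and the share at 500 kb to under 2 Mb kept their direction under every alternative. Without 1 library at a time, the difference in strength (0.10) ranged from 0.09 to 0.12, boundaries with a higher score from 564 to 675 and with a lower score from 137 to 174. Bins with a higher score ranged from 6347 to 7164 and with a lower score from 5784 to 6627. It was 0.04 for boundaries from the Del8 map, where the groups overlapped, 0.16 from the WT map, 0.07 without WT replicates 1 and 2, and 0.28 with partly lost bins kept. Depth was unequal: thinned to the smallest library, boundaries were 603 higher and 156 lower, and the corner over domain differed by -0.0181 without overlap, against -0.0078 with overlap.

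Higher and lower boundaries were 405 and 115 with a 1 Mb square (of 775), 418 and 85 at prominence 0.5 (of 757), 812 and 106 on the WT map, 450 and 239 on the Del8 map, 376 and 394 with each library centred, and 0 and 0 with partly lost bins kept. The cause was not tested, except that fewer boundaries were tested in the first 2. Partly lost bins also reversed the boundaries at 26900001 on chromosome 2 (1.42) and 27500001 on chromosome 14 (0.83).

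The corner over domain reversed on the WT map (0.0052), with raw counts (0.0188) and with partly lost bins (0.214). The share at 50 kb to under 500 kb ranged from -2.95 to 0.549 without 1 library, and reversed without WT replicate 1 (0.549) or 2 (0.387), ICE-balanced (0.387), on usable bins (0.520) and without both (3.88). The share at 2 Mb to under 10 Mb ranged from -0.564 to 0.230, reversing without WT replicate 3. Compartment strength ranged from -0.222 to -0.0713 without 1 library, and reversed with partly lost bins (0.781) and without WT replicates 1 and 2 (0.0664). Contact among A bins reversed with partly lost bins (0.0643), and between A and B, which ranged from -0.00034 to 0.0241 without 1 library, without WT replicate 1 (-0.00034), with partly lost bins (-0.127) and without WT replicates 1 and 2 (-0.0228). The cause was not tested.

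Bins with a higher and a lower eigenvector, 0 and 0 as designed, ranged up to 4 and 3 without 1 library. They were 87 and 100 without scaling, 11 and 16 at 500 kb, 2 and 3 after thinning, 100 and 93 on 12 chromosomes, 303 and 600 with the correlation matrix and 259 and 134 with log values. With log values the bin at 38250001 on chromosome 3 reversed (0.54). The cause was not tested. Chromosomes with a higher and a lower share ranged from 0 to 2 and from 0 to 16.

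Bin pairs with more and fewer contacts ranged from 4302 to 5528 and from 3664 to 4875 without 1 library. They were 2200 and 4136 with DESeq2 (which gave an adjusted p for 84415 pairs), 2393 and 2075 without WT replicates 1 and 2 (1 WT library), and 2663 and 2237 of 338495 with 50 kb bins. TMM factors gave 7038 and 8230. Leaving out chromosomes of different coverage was not run, since no chromosome passed.

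Equal replicate numbers did not pair the libraries: deviations from the group means correlated at -0.04, -0.04 and -0.08 for insulation. With the replicate number as a block, boundaries were 628 higher and 161 lower, bins 7052 and 6554, and bin pairs 6732 and 5746.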

Other observations

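Contacts on the mitochondrial genome, which entered no comparison, numbered 438, 492 and 544 in WT replicates 1 to 3 and 242, 278 and 204 in the deeper Del8 libraries, replicates 1 to 3. Boundaries called on the summed map of each group numbered 1335 in WT and 1160 in Del8, of which 875 lay within 1 bin of each other.

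The following test of all divisions of the libraries was chosen after the results were seen. The 6 libraries can be split into 3 and 3 in 10 ways. As many calls as the real grouping gave were reached in 1 of the 10 splits, the real one, for boundaries (812, at most 0 in the others), for insulation per bin (13869, at most 0) and for bin pairs (13451, at most 0). For the eigenvector and for chromosome coverage all 10 splits did so, since the real one gave 0. A count of 10 splits cannot give a share under 0.1.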
